A study of Mus musculus with 4 samples.

How the data were processed

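Genomic DNA of wild-type and LSH knockout ES cells and MEFs was sonicated, and fragments with 5hmC were glucosylated with an azide-bearing glucose, biotinylated by click chemistry and captured on streptavidin beads before library preparation, per the labels' protocols. Reads were aligned with BWA and handled with SAMtools 1.3.1 on mm9, per the submitters' processing notes, which give these names without their role. How reads were counted, which program called the differential bins, its threshold and whether an input library was used are not given in the sources used here. The values deposited by the authors are other than measurements of level: each list holds a chromosome, a start, an end and a running bin number for every 5 kb bin called differential, and no count, fold, p-value or direction. Each of the 4 groups has 1 library. No value per library was used, the read depth is unknown, and no replicate error, floor or interval on 5hmC itself can be given.

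The lists were read as deposited, and positions are printed 1-based. The reference was NCBIM37, the assembly also called mm9, with the GENCODE M1 annotation. The build was checked from the files. The running bin numbers of 8547 of 8547 ES bins and 8975 of 8975 MEF bins on chromosomes 1 to 19, X and M equalled the cumulative bin numbering of the reference. The last MEF bin of chromosome 13 ended at 120284312, the length of that chromosome. No bin was listed more than once. Analyses used chromosomes 1 to 19 and X. Bins with over 50% undetermined bases were left out of all steps that needed sequence content, leaving 511186 bins; 1 listed MEF bin was among those left out.

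For each bin the GC content, the CpG count per kb and a repeat measure were computed. The genome sequence was not masked for repeats, so the share of 32-base words that occur more than once in the genome was used instead, from a fixed sample of 1 word in 64. The annotation of repeat families was not analysed here. Genes were the 26031 protein-coding, lincRNA and processed transcript models with distinct names, the longest locus being kept for a repeated name. A bin was a promoter bin if it overlapped the 1 kb either side of a transcription start, otherwise an exon bin if it overlapped an exon of any model, otherwise intron or intergenic. In the annotation, 7 models contained 10 or more other genes. Symbols of the lists were matched by name or through synonyms in a RefSeq gene table of assembly GRCm38.p6, used for names only; 38 of 42 imprinted, 27 of 28 methylation and 49 of 50 developmental symbols were found, and all symbols of the other 7 lists.

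Overlap of the lists, shares by class and position in genes were tested by circular shift of a list within each chromosome, between its first and last listed bin, with 1000 draws. A permutation p is the share of draws, the observed value included, that lie at least as far from the mean of the draws as the observed value. Touching bins, shares per chromosome and 2 added overlap tests used bins redrawn at random within strata. These strata were 10 groups of CpG density, 5 of GC content, repeat classes divided at 5%, 20% and 50%, and gene class, or chromosome, CpG density and gene class. Redrawn bins do not keep the touching of listed bins, so for chromosomes and overlap the ranges may be too narrow and the p-values too small. Gene lists were compared with 10000 random lists with the same number of genes in each of 10 length groups. Differences between cell types used 10000 permutations of cell type over stretches merged within 10 kb, or Fisher's exact test on genes. The class differences within groups of like CpG and GC content used 1000 permutations of cell type within these groups, over the 17516 listed bins with sequence, a bin on both lists entering once for each. These permutations likewise do not keep the touching of listed bins, so their ranges may be too narrow. All tests are two-sided except the chi-square and variance permutations and the shuffling of chromosome parts, and p-values were adjusted by Benjamini-Hochberg within each family of 20 list tests, 8 class tests, 40 chromosome tests and 10 position tests. Bins and genes are not replicates, so these p-values describe the lists and not the spread between cultures. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.

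The tests were run on simulated lists before the real ones. For the overlap of ES and MEF lists over 511186 bins, 400 planted common bins were detected in 40 of 40 runs, with a median fold of 3.64 where 3.63 was planted; without planting, 2 of 40 runs had p below 0.05. For the class test of one list over 511186 bins, a planted weight of 2 on exon bins was detected in 40 of 40 runs, with a median fold of 1.70 where 1.71 was planted, against 3 of 40 without. For gene lists of 40 among 26031 genes, 12 planted genes were detected in 40 of 40 runs, against 2 of 40 without. Without planting, bins were drawn evenly and independently over the genome, and list genes at random. The rates therefore do not cover touching bins, CpG-rich lists or neighbouring list genes that share bins.

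The design fixed before the data were examined also had counts of gained and lost bins, their split between cell types, the direction of bins on both lists and effect sizes. These parts, and all stricter thresholds, were not run because the lists hold no direction, effect or p-value; counts of listed bins stand in their place. Named stretches were, by the rule fixed then, the 10 merged stretches with the greatest listed length per cell type, ties by position. Named genes were the 10 with the most bins per cell type and, per fixed list, up to 10 genes by number of bins; some genes of a list beyond these 10, the examples among receptor genes with equal counts, and the Hells locus were named after their values were seen. Not all stretches and genes that this rule chose are named in the text, with several lists given as counts with examples, and some results are not reported here. Alternatives fixed at the same time were merging of bins, autosomes only, covered length, wider overlap, redrawing from the pooled positions, a wider promoter, the bin midpoint, promoters only, and lists matched also on chromosome. Matching on CpG, GC, repeat content or CpG density of genes, leaving out chromosomes 14, 15, 17 and 19, leaving out wide gene models, and circular shift for gene lists were added after seeing the data.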

Results

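Genomic 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine made by the TET enzymes, was profiled in mouse embryonic stem (ES) cells and in mouse embryonic fibroblasts (MEFs). ES cells are pluripotent cells derived from the early embryo, and MEFs are connective tissue cells cultured from the later embryo. In each cell type, wild-type cells were set against cells lacking LSH, the SNF2-family chromatin remodeler encoded by Hells. DNA fragments that carry 5hmC were tagged with an azide-glucose, biotinylated, captured on streptavidin and sequenced. There were 4 libraries, 1 per genotype and cell type, so no value has a replicate error. The data analysed are 2 lists of 5 kb bins of the mm9 genome that the authors called differential between knockout and wild type, 1 list per cell type. The lists give positions only. They hold no direction of change, level, fold change or p-value, and the read depth of the libraries is unknown. A listed bin is therefore described as altered, without saying whether 5hmC was higher or lower. Intervals in brackets are exact 95% binomial intervals and cover counting error over bins, which are not replicates.

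The first question was which parts of the ES cell genome were altered without LSH. The altered stretches with the most listed bins, after joining bins within 10 kb, lay at Zfp704 and Ppp2r5c, each with 5 listed bins. The Zfp704 stretch (chromosome 3, 9450001 to 9495000) had 2 bins over exons and 3 in introns of this zinc finger gene. The stretch at Ppp2r5c, which encodes a regulatory subunit of protein phosphatase 2A, spanned chromosome 12, 111660001 to 111695000, with 1 promoter bin, 1 intron bin and 3 intergenic bins. The other named stretches had 4 listed bins each. They lay at Nrp2, a receptor for semaphorins and VEGF (chromosome 1, 62790001 to 62820000), at Srp9, a signal recognition particle subunit (chromosome 1, 184040001 to 184075000), and in introns of the ubiquitin ligase gene Trim2 (chromosome 3, 84035001 to 84080000). Further ones lay at Dapp1 (chromosome 3, 137605001 to 137645000), at the postsynaptic scaffold gene Dlgap3 (chromosome 4, 126875001 to 126915000) and at Plekha5 (chromosome 6, 140360001 to 140395000). The last lay at the homeobox genes Hmx3 and Hmx2 beside Bub3 (chromosome 7, 138680001 to 138710000) and at Ndrg4 (chromosome 8, 98195001 to 98225000). In total 8557 bins were listed, of which 8545 lay on chromosomes 1 to 19 and X. These covered 42.7 Mb, or 1.67% of the 511186 bins with sequence [1.64% to 1.71%], and joined into 7413 stretches.

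Among genes with an ordinary model, Tshz2, a teashirt-family zinc finger gene, had the most ES bins in the body or within 5 kb upstream, with 12. Ank3, the ankyrin G gene, Odz4 and Wwox had 10 each. Pde4d, Sox5 and St3gal3 had 9 each, and Arhgap26 had 8. The gene models of Gm20388 (50 bins, 84 other genes inside it) and Fgfr2 (35 bins, 37 other genes inside it) ranked higher. These models span 4434882 and 3009069 bp in the annotation used, so their bins cannot be assigned to a single gene. The counts are not scaled by gene length. The ordinary models named ran from 202761 bp (St3gal3) to 1503528 bp (Pde4d), both with 9 bins, so a higher count need not mean denser alteration.

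In MEFs the stretch with the most listed bins, 9, lay beside Eln, the elastin gene (chromosome 5, 135220001 to 135275000), 1 of them a promoter bin and 8 intergenic. Stretches of 8 bins included those at Gas6, the ligand of the TAM receptor kinases (chromosome 8, 13480001 to 13565000), and at Edar, the ectodysplasin receptor gene (chromosome 10, 58070001 to 58140000). Another 8-bin stretch was intergenic, 1.67 kb from Blk (chromosome 14, 63935001 to 63990000). Stretches of 7 bins lay at Mapkap1, a subunit gene of the TOR complex (chromosome 2, 34440001 to 34490000), at the secreted WNT antagonist gene Sfrp1 (chromosome 8, 24540001 to 24595000) and at Nkd1, a WNT pathway inhibitor gene (chromosome 8, 91085001 to 91130000). One more lay inside Gm20388 (chromosome 8, 123855001 to 123910000). The last 7-bin stretch, at the proximal end of chromosome 9 (3000001 to 3040000), lay over an array of predicted genes. Of its sampled 32-base words, 88.5% occur more than once in the genome, so its reads are hard to place. In total 9002 bins were listed, 8972 of them on chromosomes 1 to 19 and X, covering 44.9 Mb or 1.76% of bins [1.72% to 1.79%]. They joined into 6892 stretches, fewer than in ES cells although more bins were listed.

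MEF genes with many listed bins were Prkce, which encodes protein kinase C epsilon (22 bins, against 8 in ES cells), and Cacna2d3, a calcium channel subunit gene (20 bins, against 1). They were followed by 1700112E06Rik (19, against 0), Pdzd2 (18, against 2), Enox1 (16, against 5), Wwox (14, against 10), Adamtsl1 (13, against 1) and Erc2 (13, against 1). Of these, Prkce lies on chromosome 17, Pdzd2 on 15, and Cacna2d3, 1700112E06Rik, Enox1 and Erc2 on 14, chromosomes with more MEF bins than matched bins gave as a whole (1.27-fold, 1.70-fold and 1.39-fold). Gm20388 held 83 bins and Fgfr2 held 15. The MEF counts are likewise not scaled by gene length, which ran from 374471 bp (Adamtsl1) to 1036374 bp (1700112E06Rik) in the other genes named. Hells itself (chromosome 19, 39005405 to 39045541) had 0 listed bins in either list. Listed bins also touched one another more often in MEFs. Of the MEF bins, 1013 directly followed another listed bin, 3.74 times the 271 in bins redrawn with the same chromosome, CpG density and gene class. In ES cells the number was 448, 1.54 times the expected 290. Both had permutation p = 0.001, the smallest that 1000 draws can give.

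Altered bins in both cell types were rich in CpG, the dinucleotide at which most mammalian cytosine methylation lies. The median was 12.6 CpG per kb in ES bins and 11 in MEF bins, against 7 in all bins. Median GC content was 46.4%, 45.3% and 41.2%. All bins with sequence served as the background, whether or not 5hmC could be detected there, since no level was given. These values therefore cannot separate where LSH loss acts from where a change could be detected. When bins were split into 10 equal groups by CpG density, the listed share in ES cells was 0.0196% in the lowest group [0.00938% to 0.036%] and 5.6% in the highest [5.4% to 5.8%]. In MEFs it was 0.131% in the lowest group and peaked in the group below the highest, at 4.25% [4.07% to 4.43%], against 3.69% in the highest [3.53% to 3.86%]. Bins made mostly of repeated sequence were rare, 10 in ES cells and 38 in MEFs, although they form 10.2% of the genome. Reads are hard to place in such bins, so the lists cannot show whether 5hmC in repeated sequence was unaltered.

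**Figure D1:**
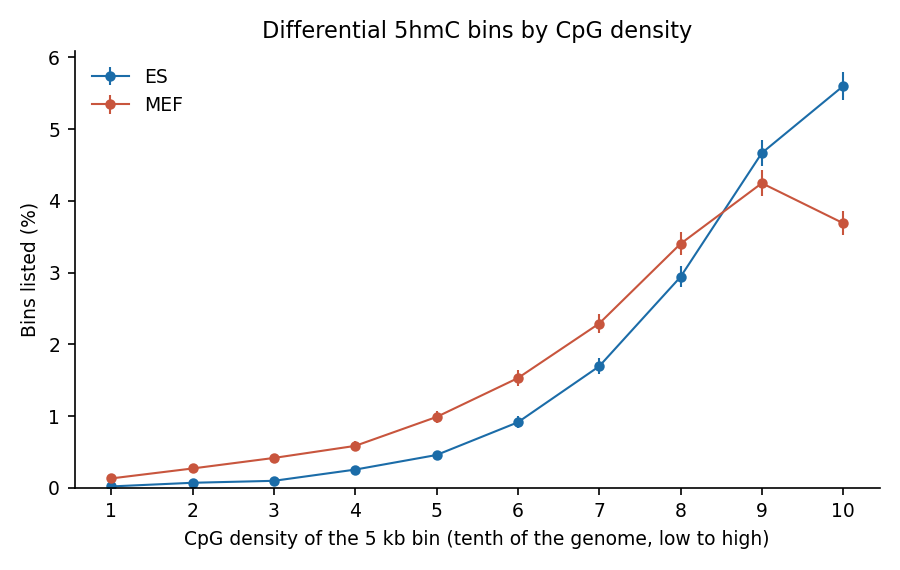
Percent of 5 kb bins listed as differential (y axis) in 10 equal groups of bins ordered by CpG density (x axis), for ES cells and MEFs, with exact 95% binomial intervals. The listed share is highest in group 10 in ES cells (5.6%) and in group 9 in MEFs (4.25%).

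The next question was where in genes the altered bins lay. By fold over circular shifts, exon bins led in ES cells and intron bins in MEFs, while the class with the largest share was exon in ES cells and intergenic in MEFs by any overlap, and intron in both by bin midpoint (53.7% and 52.1%). By any overlap each bin had 1 class, promoter (within 1 kb of a transcription start), otherwise exon, otherwise intron, otherwise intergenic. In ES cells 34.7% of listed bins were exon bins [33.7% to 35.7%], 1.96 times the share after circular shifts of the list along each chromosome (permutation p = 0.001, adjusted permutation p = 0.00114). Against bins drawn at random with the same CpG and GC content, in place of shifted lists, it was 1.3-fold. In MEFs 31.8% were intron bins [30.8% to 32.8%], 1.43-fold over the shifted lists (permutation p = 0.001) and 1.45-fold over matched bins. Intron bins in ES cells were 23.6%, 1.07-fold (permutation p = 0.019), but by bin midpoint the intron fold was 1.41 in ES cells and 1.36 in MEFs (permutation p = 0.001 each), so the contrast in introns depended on the class rule. Intergenic bins were fewer than in shifted lists in both, with 30.0% in ES cells (0.558-fold) and 38.5% in MEFs (0.721-fold). Shifted lists and matched bins may likewise take in bins where no change could have been detected.

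Promoter bins made up 11.7% of the ES list and 8.65% of the MEF list, more than in shifted lists (1.77-fold and 1.31-fold, permutation p = 0.001 each) but less than in bins matched on CpG and GC (0.807-fold and 0.795-fold, permutation p = 0.001 each). MEF exon bins, at 21.1%, likewise went from 1.19-fold against shifted lists (permutation p = 0.001) to 0.867-fold against matched bins, and by bin midpoint they were 1.09-fold against shifted lists, not past the threshold (permutation p = 0.166). The 2 lists differed in class by any overlap. With 1 library per genotype and the depth and caller unknown, a difference between the cell types cannot be told apart from one in how the lists were made. The exon share was 13.7 percentage points higher in ES cells and the intron share 8.24 points lower in ES cells, by permutation of cell type over merged stretches (p = 0.0001 each, the smallest that 10000 draws can give). By bin midpoint the exon difference was 4.12 points (7.34% against 3.22%, permutation p = 0.0001), and the intron difference turned to 1.58 points, not past the threshold (permutation p = 0.0747). Within groups of bins of like CpG and GC content the exon and intron differences by any overlap were 11.2 and -6.45 points (ES minus MEF, permutation p = 0.001 each), while the promoter difference of 3.09 points was no longer past the threshold, at 0.386 points (permutation p = 0.412).

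**Figure D2:**
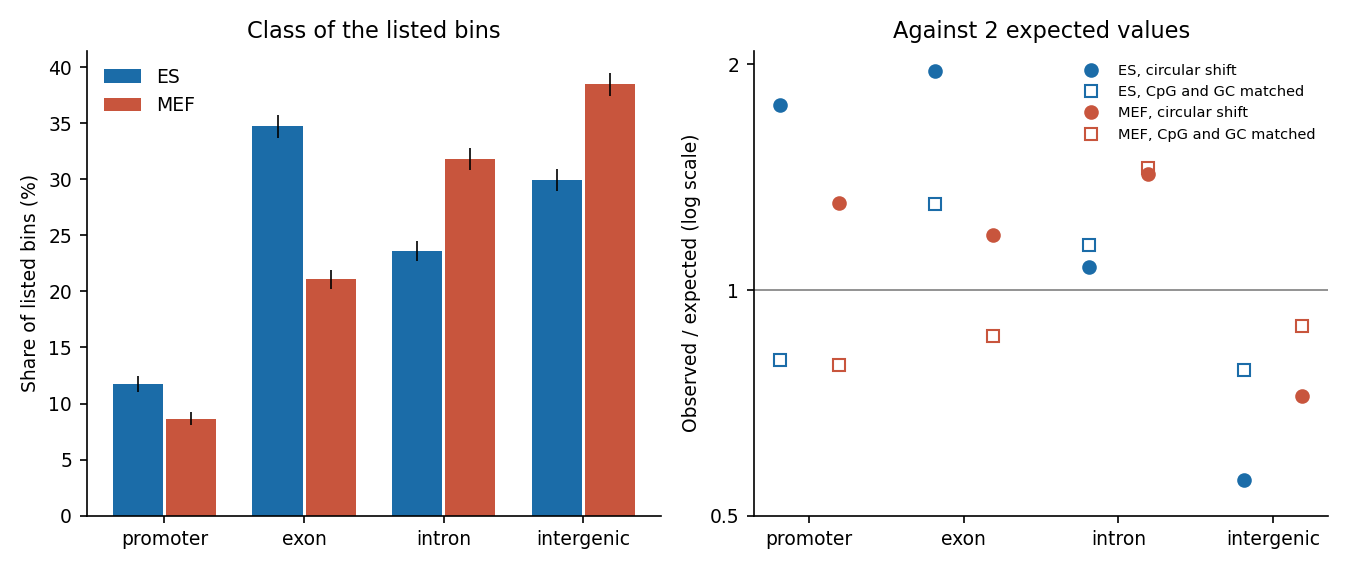
Left, percent of listed bins in each class (bars) with exact 95% binomial intervals, for ES cells and MEFs. Right, observed share over the expected share on a log scale, against circular shifts (filled circles) and against bins matched on CpG and GC (open squares); promoter bins in both lists and MEF exon bins lie above 1 with the first and below 1 with the second.

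Among 10 gene lists fixed before the data were examined, Hox genes, developmental regulators, and olfactory and vomeronasal receptors departed from length-matched random lists in ES cells. Of 39 Hox genes, the homeobox genes that pattern the body axis, 12 had an altered bin, 2.5-fold over expectation (adjusted permutation p = 0.00733 over 20 tests). Neighbouring Hox genes shared bins, so the 12 genes rested on 7 distinct bins. One bin in the Hoxa cluster (chromosome 6, 52160001 to 52165000) served Hoxa3, Hoxa6 and Hoxa7, and one in the Hoxb cluster (chromosome 11, 96160001 to 96165000) served Hoxb5 and Hoxb6. In the Hoxc cluster Hoxc10, Hoxc9, Hoxc6, Hoxc5 and Hoxc4 were reached by 3 bins on chromosome 15, at 102800001, 102835001 and 102855001. Hoxd3 and Hoxd4 shared 2 bins on chromosome 2, at 74560001 and 74565001. With the random lists matched also on CpG density the Hox list was no longer past the threshold (1.59-fold, adjusted permutation p = 0.434), nor was it when only promoters were counted (4 genes, 1.94-fold, adjusted permutation p = 0.664).

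Of 49 developmental regulators, 16 had an ES bin (1.83-fold, adjusted permutation p = 0.034). Pax5, a B-cell lineage factor gene, had 3 bins. Pax2, Gata2 and Gata4 had 2 each, and Gata4, a factor of heart and endoderm, shared an intronic bin with the MEF list (chromosome 14, 63850001 to 63855000). Promoter bins lay at Gsc (chromosome 12, 105710001 to 105715000), Sox7 (chromosome 14, 64560001 to 64565000) and Gata2 (chromosome 6, 88140001 to 88145000). Among those with 1 bin were Dlx1, Pax3, Six2, Lhx2, Pax1, Gata3, Cdx1, Tbx5 and Tbx15. With CpG density matched, this call was also lost (1.2-fold, adjusted permutation p = 0.535), as it was with promoters only (3 genes, 1.28-fold, adjusted permutation p = 0.987). Of 1451 olfactory and vomeronasal receptor genes only 8 had an ES bin, 0.1-fold (adjusted permutation p = 0.001), and 0.687-fold with CpG matched (adjusted permutation p = 0.449). These 8 genes rested on 6 distinct bins. Among them were Olfr324, Olfr750 and Olfr56. The Olfr56 model spans 156499 bp and contains 5 other genes, so its bin cannot be assigned to the receptor alone.

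The other ES lists did not pass the threshold. Of 27 genes for DNA methylation, hydroxymethylation and LSH partners, 11 had a bin (1.53-fold, adjusted permutation p = 0.209). Tet1 and Tet3, which oxidise 5-methylcytosine, had 1 bin (chromosome 10, 62325001 to 62330000, exon) and 2 bins (chromosome 6, from 83315001 and from 83350001, exon). The methyltransferase genes Dnmt1 (chromosome 9, 20720001 to 20725000), Dnmt3b (chromosome 2, 153485001 to 153490000) and Dnmt3l had 1 each, and Dnmt3a had 2. Idh2 and the demethylase gene Kdm1a had 2 each, and Tdg, Mbd2 and Hdac1 had 1 each. Of 38 imprinted genes, 13 had a bin (1.5-fold, adjusted permutation p = 0.202). Igf2r led with 4 adjacent exon bins (chromosome 17, 12880001 to 12900000), followed by 2 bins at Trappc9 and 2 that Gnas shared with its antisense transcript Nespas. Peg3, Rasgrf1, H13, Sgce, Impact, Rtl1, Ascl2, Slc22a3 and Airn had 1 each. Of 30 pluripotency genes, 7 had a bin (1.35-fold, adjusted permutation p = 0.586). Esrrb had 2 intron bins, Lefty2, Tcl1, Otx2 and Dppa3 had promoter bins, and Klf5 and Sox2 had 1 bin each. Germline genes (7 of 32, Asz1 and Tdrd1 among them), fibroblast genes (5 of 30), clustered protocadherins (5 of 24, Pcdhgc5 with 3 bins) and Zfp genes (57 of 369, Zfp536 with 8 bins) had adjusted permutation p of 0.797, 0.464, 0.516 and 0.117. Against circular shifts of the bins, which do not match gene length, the imprinted, pluripotency and methylation lists passed as well (2.44-fold, 2.93-fold and 2.93-fold, adjusted permutation p = 0.015, 0.0114 and 0.004). So did the Zfp list, in the opposite direction to the length-matched comparison (1.5-fold, adjusted permutation p = 0.0156, against 0.794-fold).

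In MEFs, 11 of 30 fibroblast genes had an altered bin, 1.95-fold over length-matched lists, without passing the adjusted threshold (permutation p = 0.0144, adjusted permutation p = 0.0576). It passed with lists matched on length and chromosome (2.05-fold, adjusted permutation p = 0.0248) and against circular shifts (2.81-fold, adjusted permutation p = 0.004). It did not pass with CpG density matched (1.83-fold, adjusted permutation p = 0.154), without wide gene models (1.94-fold, adjusted permutation p = 0.0516) or with promoters only (1 gene, 0.958-fold, adjusted permutation p = 1). The collagen genes Col6a3 (2 bins, chromosome 1, 92690001 to 92700000, exon), Col6a2, Col5a1 and Col1a2 were among them. So were Pdgfra and Pdgfrb, the PDGF receptor genes, Tgfbr2 with 2 intron bins, Prrx1, Mmp2, Thy1 and S100a4. Of the Hox genes 7 had a bin (2.38-fold, adjusted permutation p = 0.0657), through 6 distinct bins. Hoxb3 alone had 4 of them, from 96180001 to 96210000 on chromosome 11, and Hoxb2 and Hoxb4 shared 1 each with it. Hoxc11 had 1 bin. Olfactory and vomeronasal receptors were again few, at 8 of 1451 through 7 distinct bins (0.145-fold, adjusted permutation p = 0.001). With CpG matched they were 0.479-fold (adjusted permutation p = 0.154).

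The other MEF lists did not pass the threshold. Of the imprinted genes 10 had a bin (1.58-fold, adjusted permutation p = 0.202), Grb10 with 4 (chromosome 11, from 11830001 to 11915000), Slc22a2 and Trappc9 with 2, and Plagl1, Rian, Slc22a3, Airn, Gnas, Peg3 and Sgce with 1. Of the methylation genes 4 had a bin, namely Tet1, Dnmt3a, Dnmt3b and Uhrf2 (0.809-fold, adjusted permutation p = 0.817). Pluripotency genes (2 of 30, Fgf5 and Dppa5a), germline genes (5 of 32) and protocadherins (1 of 24, Pcdhgc5) had adjusted permutation p of 0.555, 0.817 and 0.586. Zfp genes (32 of 369, Zfp423 with 11 bins) had an adjusted permutation p of 0.0627. Among developmental regulators (5 of 49, adjusted permutation p = 0.817) Gata4 and Pax8 had 3 bins, Gata3 had 2 and T and Gata5 had 1. Whether a list differed between the cell types was tested on genes altered in 1 cell type only. None of the 10 lists passed (Fisher's exact test, two-sided), the fibroblast list coming nearest with 3 genes in ES cells only and 9 in MEFs only (p = 0.0123, adjusted p = 0.123).

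**Figure D3:**
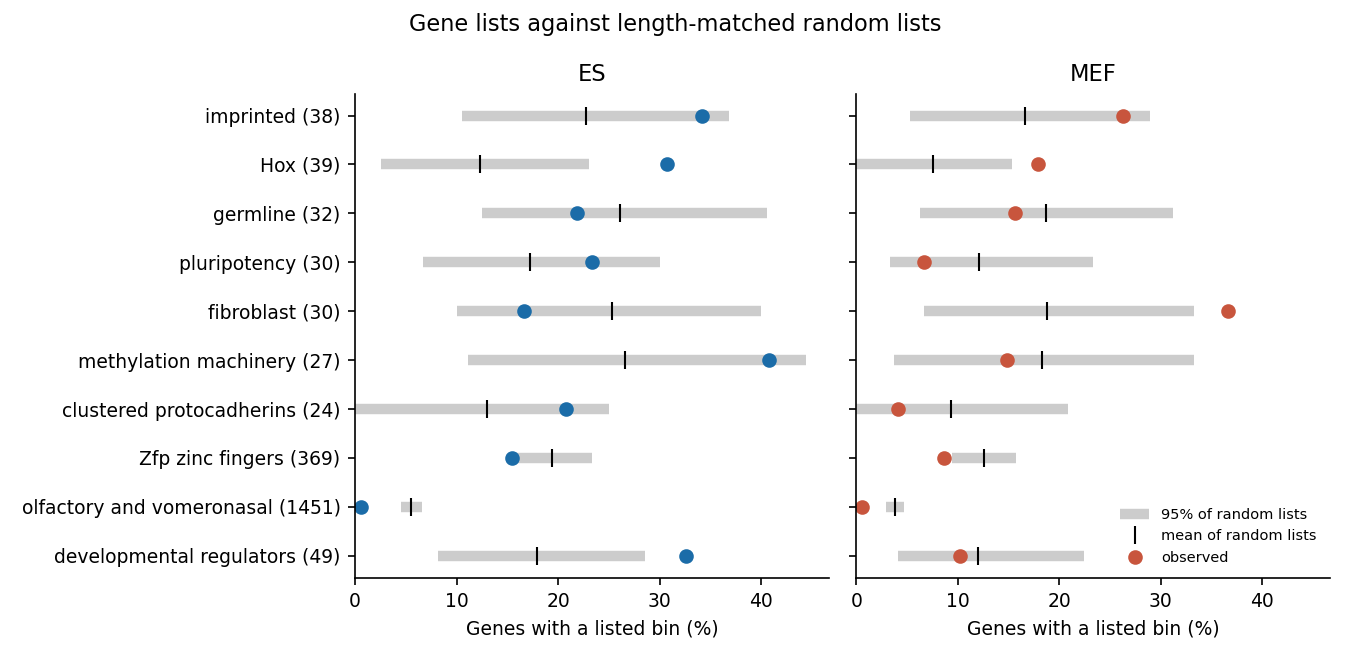
Percent of the genes of each list with a listed bin in the gene body or within 5 kb upstream (points), with the mean (tick) and 95% range (grey bar) of 10000 length-matched random lists, for ES cells and MEFs; numbers in brackets are genes per list. Hox genes and developmental regulators lie above the range in ES cells, Hox and fibroblast genes lie above it in MEFs, and receptor and Zfp genes lie below it in both.

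**Figure D4:**
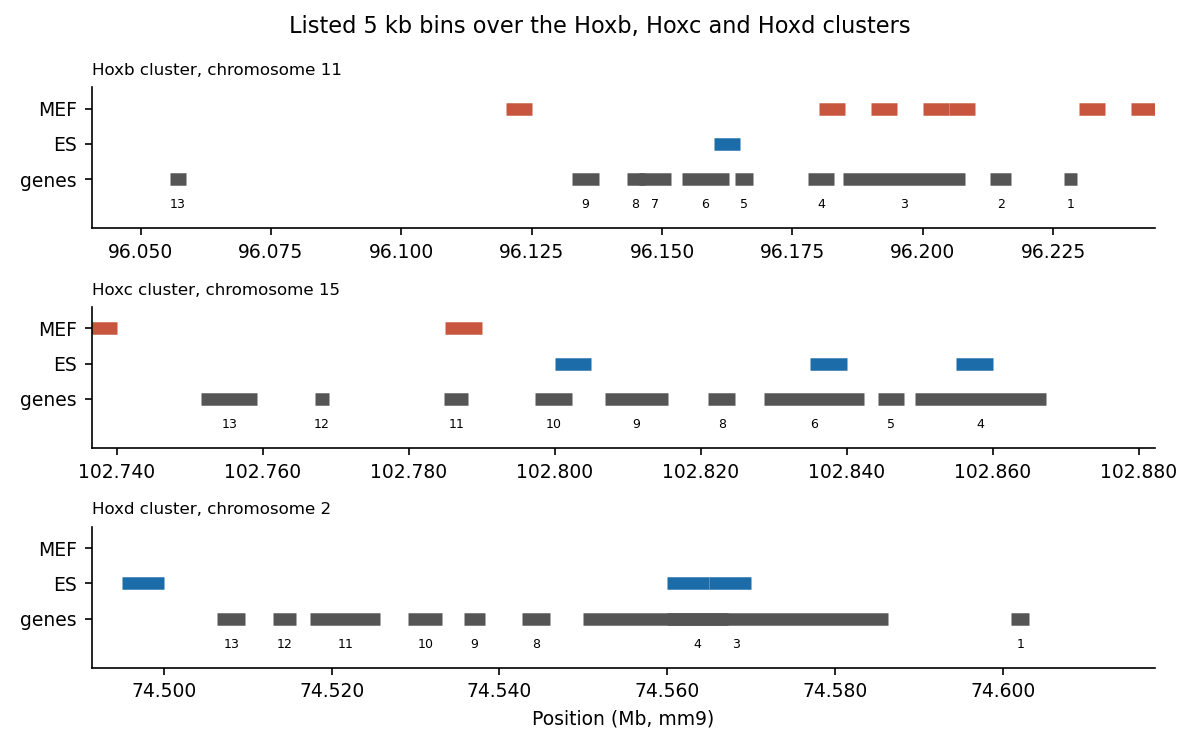
Listed 5 kb bins (blue, ES cells; red, MEFs) over the Hoxb, Hoxc and Hoxd clusters, with gene models in grey and their numbers below; the x axis is the mm9 position in Mb. Neighbouring genes share bins, and the Hoxb window as drawn holds 7 MEF bins and 1 ES bin.

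The lists were then compared to ask whether the same places were altered in both cell types. Gata4 and Prkce were among the genes with a bin in both, Prkce with 4 bins in common. In total 406 bins were on both lists, 4.75% of the ES bins and 4.53% of the MEF bins. This was 2.42 times the 167 found after circular shifts (95% range 140 to 196, permutation p = 0.001). In place of shifts, MEF bins redrawn with the same CpG density, GC content, gene class and repeat content shared 347 bins (314 to 381), against which the overlap was 1.17-fold (permutation p = 0.001). Of the 26031 gene models, 5164 had an ES bin, 3661 a MEF bin and 1535 both. That was 1.37 times the number in lists matched on length (1119) and 1.12 times the number matched on length and CpG density (1370), permutation p = 0.0001 each. Neighbouring and nested gene models share bins, which random gene lists do not keep, so these p-values may be too small. Only 293 of these genes had a bin on both lists at the same place.

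Finally, the chromosomes were compared. In MEFs the listed share was highest on chromosome 19, at 4.26% [3.9% to 4.64%], on chromosome 15, at 3.23% [2.99% to 3.48%], and on chromosome 17, at 2.66% [2.43% to 2.9%]. It was lowest among autosomes on chromosome 12, at 0.932% [0.813% to 1.06%]. Against bins matched on CpG, GC, gene class and repeat content, the number on chromosome 19 was 1.86-fold, on 15 1.70-fold, on 14 1.39-fold, on 7 0.586-fold and on 12 0.567-fold, with an adjusted permutation p of 0.00267 each over 40 tests. In MEFs 15 of 19 autosomes passed the threshold, 7 of them with more bins than matched. In ES cells matched ratios over autosomes lay between 0.936 and 1.12, and 2 of 19 passed, chromosomes 11 (1.09-fold) and 17 (1.12-fold). The redrawn bins did not keep the touching of listed bins, which was 3.74-fold over expectation in MEFs and 1.54-fold in ES cells. Both counts of chromosomes may therefore be too high, more so in MEFs. With autosomes cut into equal parts, chromosomes explained 8.7% of the variance between parts in ES cells (9.48% after permutation, permutation p = 0.55). In MEFs they explained 51.1% (9.46% after permutation, permutation p = 0.001). The distribution over chromosomes differed between the lists (Cramér's V = 0.121, permutation over 14305 merged stretches, p = 0.0001). Chromosome X was nearly empty in both lists, with 18 ES bins and 52 MEF bins against 140 (117 to 163) and 188 (162 to 215) expected from matched autosomal bins, or 0.129-fold and 0.277-fold. No bin of the 541 with sequence on chromosome Y was listed.

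**Figure D5:**
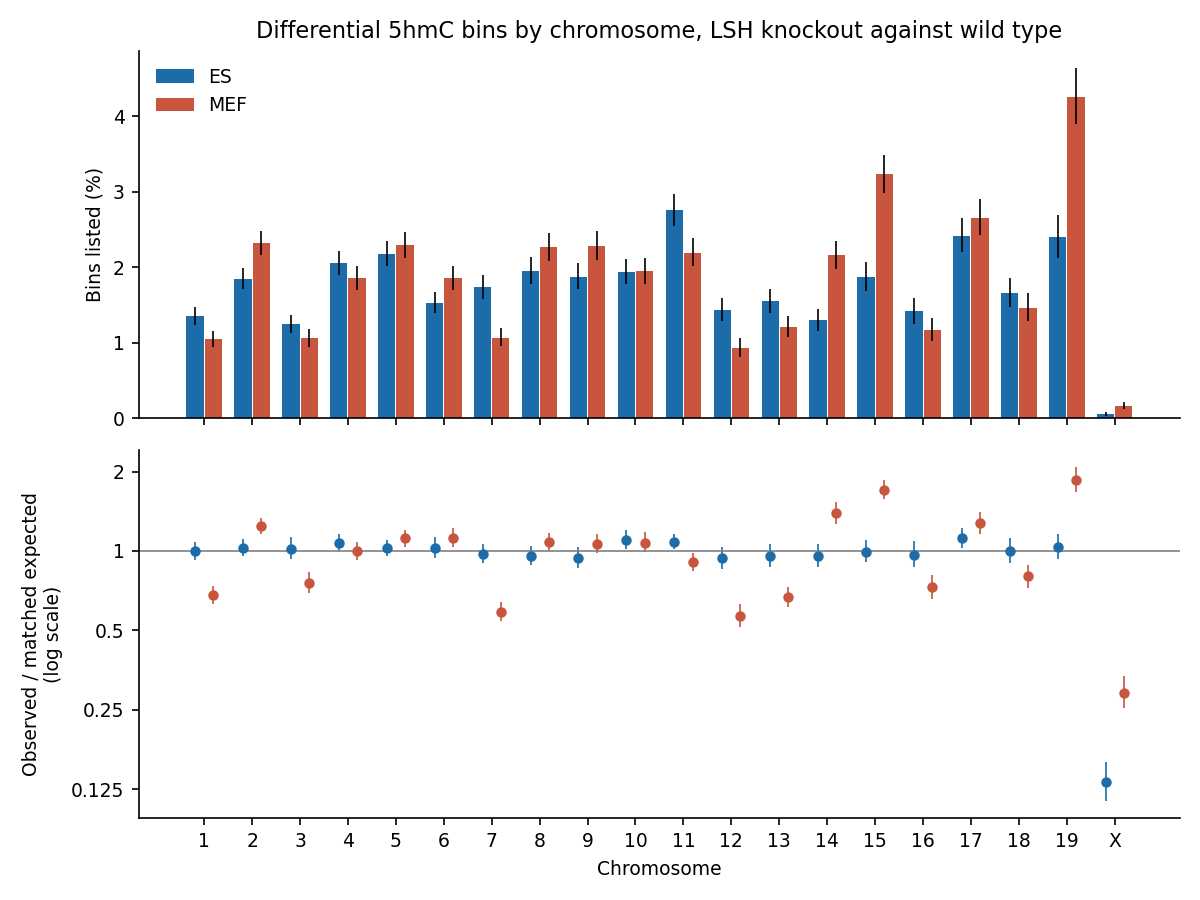
Top, percent of bins listed per chromosome with exact 95% binomial intervals, for ES cells and MEFs. Bottom, number listed over the number expected from bins matched on CpG, GC, gene class and repeat content (log scale), with the range from the 95% range of draws; ES autosomes lie between 0.936 and 1.12, MEF autosomes between 0.567 and 1.86, and X lies below all of them.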

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

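The removal test for chromosome X, both tests of the overlap and the shuffling of chromosome parts were chosen only after the result was seen, as was the comparison of classes within groups of like CpG and GC content.

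Chromosome X held few altered bins in both cell types. Its sequence and gene content did not account for this, since matched autosomal bins gave 140 ES bins and 188 MEF bins against 18 and 52 observed, ratios of 0.129 and 0.277 that lie below the range of draws. Removal of X before testing is argued against by the bins that are listed there, of which ES cells had 18, the fewer. A single X copy, which would lower the reads per bin, could lower the chance of a call, but the ratio of 0.277 in MEFs cannot be told apart from other explanations without read counts or the sex of the cells. A true difference of X from autosomes in ES cells or MEFs was not tested.

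The chromosomes differed between the lists, with a Cramér's V of 0.1205 over merged stretches (permutation of cell type, p = 0.0001). Content did not account for the MEF excess on chromosomes 19, 15 and 17, where the observed number together was 1.584 times the matched one. A gain or loss of a whole chromosome in 1 of the 2 MEF libraries is a candidate explanation, because it could change the number of called bins along the entire chromosome. Since the lists hold no direction, whether it would raise or lower that number cannot be said. On each of the 3 chromosomes 9 of 10 equal parts had more bins than matched. The 3 were chosen for the highest listed share, which favours such parts. With parts shuffled over the autosomes and the 3 highest chosen again, the fewest such parts on any of them was 6 in the median draw. The 95% range was 4 to 7 (permutation p = 0.0001, the smallest that 10000 draws can give). Shuffling separates neighbouring parts, so it does not exclude changes over stretches longer than 1 part. It also removes every difference between chromosomes, and the variance of the same parts, given below, already held such differences. The shuffling result therefore adds no separate support for a change of copy number. On the other chromosomes with more bins than matched, 14, 5, 6 and 2, the number of such parts was 8, 8, 8 and 7. By matched ratio, chromosome 14 (1.39) stood above chromosome 17 (1.27). Among chromosomes with fewer bins than matched, the ratios on 12, 7, 13 and 1 were 0.567, 0.586, 0.668 and 0.681. There, 1, 1, 1 and 0 of 10 parts had more bins than matched. Chromosomes explained 51.1% of the variance between parts in MEFs (9.46% after permutation, p = 0.001) against 8.7% in ES cells (p = 0.55). Any cause that acts on whole chromosomes would give such values. An effect of LSH loss on chromosomes 19, 15 and 17 in MEFs, or a difference between the cultures, was not tested and stays open, since there is 1 library per genotype.

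The overlap of 406 bins was above chance by circular shift. Shared CpG, GC, gene class and repeat content left an excess of 1.17-fold (406 against a range of 314 to 381), and strata of chromosome, CpG and gene class left 1.334-fold (271 to 335). Neither set of strata, as drawn, gave the whole overlap. The redrawn bins did not keep the touching of listed bins, so these ranges may be too narrow. Content still varied within a group, and chromosome was not combined with GC and repeat content. Content therefore cannot be excluded as an account of the rest. Places where 5hmC responds to LSH in both cell types may account for the rest, as would a property of bins that was not matched, such as mappability or 5hmC abundance in wild type.

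The class shares by any overlap differed between the ES and MEF lists by permutation of cell type over merged stretches (p = 0.0001 each). ES minus MEF, the difference was 3.089 percentage points for promoter, 13.656 for exon, -8.241 for intron and -8.505 for intergenic bins. By bin midpoint the differences were 1.184, 4.116, 1.576 and -6.876 points, so that for introns turned direction and was not past the threshold (permutation p = 0.0747; p = 0.0001 for the others). Within groups of like CpG and GC content the promoter difference was no longer past the threshold, at 0.386 points (range of permutations -0.833 to 0.883, permutation p = 0.412), because the difference itself shrank. The range before, -0.914 to 0.924, came from merged stretches, and the later one from single bins. The exon, intron and intergenic differences within these groups were 11.16, -6.454 and -5.092 points (permutation p = 0.001 each). Permuting single bins does not keep their touching, so these p-values may be too small.

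Outside the chromosomes compared, bins were listed on the mitochondrial genome, 2 in ES cells and 3 in MEFs of its 4 bins. On unplaced sequence 10 bins were listed in ES cells and 27 in MEFs.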

How the results depend on the processing

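Matching on CpG and GC, redrawing bins within strata, matching gene lists on CpG density, circular shift for gene lists, and leaving out wide gene models or chromosomes 14, 15, 17 and 19 were added after seeing the data. The MEF list had 1.052 times as many bins as the ES list, but 0.9297 times after merging within 10 kb and 0.983 times after merging touching bins, because MEF bins touch more often. The overlap was above chance in 6 of 7 alternatives, by 1.17-fold to 2.44-fold, and fell to 0.092-fold when bins were redrawn from the pooled positions of both lists. That setting draws MEF bins only from listed positions, so its expected overlap is large by construction. An overlap of 50% of both bins is the same test as any overlap, since all bins lie on one grid. Against bins matched on CpG and GC the promoter fold was 0.807 in ES cells and 0.795 in MEFs, and the MEF exon fold was 0.867. This setting matches CpG and GC together and also replaces the circular shifts, and the part of each in the change was not tested. Within groups of like CpG and GC the promoter share of ES minus MEF fell from 3.089 to 0.386 points (permutation p = 0.412). The MEF exon fold by bin midpoint was 1.092 (permutation p = 0.166), and the intron share of ES minus MEF went from -8.241 to 1.576 points by midpoint (permutation p = 0.0747); the cause was not tested. Apart from these, class folds and ES minus MEF differences kept their direction and side of the threshold with a wider promoter, by midpoint, without wide gene models, without chromosomes 14, 15, 17 and 19, and with CpG and GC matched, though the exon difference was 4.116 points by midpoint against 13.657.

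The ES lists past the threshold numbered 3, and 1 with promoters only, 0 with CpG density matched and 7 with circular shift. For MEFs the number was 1, and 2 with chromosome matched, 0 with CpG density matched and 2 with circular shift. Circular shift does not match gene length or gene density, and with it ES Zfp genes went from 0.794-fold to 1.502-fold and passed the threshold; the cause was not tested. Leaving out wide gene models changed no list call. Alternatives on threshold, direction and effect size were not run, because the lists hold none of these. No paired analysis was possible because there is 1 library per group. Depth is unknown, so whether a bin outside the lists was unaltered or too thinly covered cannot be said.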

Other observations

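All tests in this part were chosen only after the main results were seen, and none tested an explanation.

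Along protein-coding genes of at least 50 kb, split into 5 equal parts from the transcription start, listed bins were not evenly spread. In ES cells the last part held 22.1% of listed bins, 1.11 times the share in shifted lists (adjusted permutation p = 0.0275), and the middle part 17.6%, or 0.882-fold (adjusted permutation p = 0.015). In MEFs the first part held 22.8%, 1.14-fold (adjusted permutation p = 0.015), and the last part 17.5%, 0.879-fold (adjusted permutation p = 0.0167). The difference between the cell types was not tested.

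Gene families other than the fixed lists were taken as the 95 symbol stems with at least 20 genes. Some of their genes are also on a fixed list, such as Mmp2 and Fgf5. No family passed the threshold in either cell type over 190 length-matched tests (smallest adjusted permutation p = 0.228). Before adjustment, 12 families in ES cells and 9 in MEFs had a permutation p below 0.05. The semaphorin genes, which encode axon and vessel guidance signals, were among those in both lists. Of the 20 Sema genes, 12 had an ES bin (1.92-fold, permutation p = 0.006) and 10 a MEF bin (1.94-fold, permutation p = 0.0113), and the folds were 1.83 and 2.04 with CpG density matched. In ES cells 8 of 98 Cyp genes, many of them enzymes of steroid and drug metabolism, had a bin (0.393-fold before and 0.907-fold after matching on CpG density). In MEFs 5 of the 98 had a bin (0.387-fold before and 0.733-fold after).

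Most bins on both lists stood apart from one another, though the number expected to stand together at random was not computed. The bins on both lists formed 395 separate places, of which 11 had more than 1 bin. Among these were Stk35 (chromosome 2, 129645001 to 129660000), Cdh23 (chromosome 10, 59840001 to 59860000) and Macrod1 (chromosome 19, 7210001 to 7225000).

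The rows of the ES list were not in a single order of position. Each chromosome had 3 to 5 runs sorted by position, 4 of them on 16 of 20 chromosomes, while the MEF list had 1. The runs carry no label, so no direction was read from them.

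Of the MEF chromosomes past the threshold with fewer bins than matched, chromosome 1 had 0 of 10 equal parts with more bins than matched, chromosomes 7, 12, 13 and 16 had 1 each, chromosome 18 had 2, and chromosomes 3 and 11 had 3 each.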
